A study of Rattus norvegicus with 105 samples.

How the data were processed

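Gene expression was measured in the gastrocnemius of male Sprague-Dawley rats carrying 4 implanted metal pellets, 2 in each hind limb, for 1, 3, 6 or 12 months. Per the labels, each Clariom S Rat array was hybridised with 250 ng of total RNA pooled from 2 to 3 animals, and 3 arrays were made per metal and month. The arrays are therefore replicates of pools: a p-value measures the spread between these pools, not between single rats. The 105 arrays fall into 35 groups of aluminum, cobalt, copper, depleted uranium, iron, nickel, lead, tungsten and tantalum, which served as the implanted sham control. Nickel at 12 months was not analysed here.

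The values used are the deposited log2 intensities, 1 per probe set and array. Per the labels, the authors made them by robust multi-array averaging (RMA: background correction, quantile normalization and median polish) with the R package oligo under R 4.0.1. Whether all arrays went through RMA in 1 run is not stated. The table holds 22977 probe sets. Of these, 23 control probe sets were left out and the other 22954 were tested, with no filter on dim probe sets. Gene symbols came from a gene table for the rat assembly GRCr8, matched by gene ID: 14855 probe sets had 1 symbol and 8099 had none here. Mical2, Tagln3 and Yif1b were each on 2 probe sets, and the brighter one of each represented the gene. No coordinates are given, because the build behind the array's annotation is not stated. Array medians lay between 6.36 and 6.54. The control probe sets gave a background with a median of 4.10, and between 88.5% and 94.9% of an array's probe sets lay above that array's own control median. The number of arrays limits the precision of every value.

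Tests were run in limma 3.58.1 under R 4.3.3. A linear model with 1 mean per group was fitted to all 105 arrays (lmFit and eBayes; 70 residual and 7.25 prior degrees of freedom), so that all groups share 1 estimate of the spread per probe set. Each metal was compared with tantalum of the same month, in 31 comparisons, and as the equally weighted mean over its months, in 8 more. Further comparisons asked, for each metal, whether the difference from tantalum changed between months (moderated F); how tantalum muscle at 3, 6 and 12 months differed from 1 month; how 12 months differed from 1 month over the 8 metals with both, tantalum included; and whether the 8 metals other than tantalum differed among themselves over months 1, 3 and 6. These are 52 comparisons. All tests are two-sided, with Benjamini-Hochberg adjustment over the 22954 probe sets of a comparison and an adjusted p below 0.05 as the threshold. No minimum fold change was set. By chance alone, 1148 probe sets of a comparison would have an unadjusted p below 0.05.

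The lists of 34 gene groups cover metal handling, oxidative and protein stress, leukocytes and inflammation, matrix, muscle fibres and their regeneration, energy metabolism, the cell cycle, other cell types of muscle, blood, and daily or hormonal rhythms. Shifts of a list were tested with camera, with the correlation between genes estimated from the residuals and adjustment over 1054 tests for the months and 272 for the means. A family of 136 tests of the lists over time was added after the data were seen. Of the month tests, 16 passed, and all 16 also passed with camera's preset correlation of 0.01 (161 in all) and with the rotation test fry (47 in all), which asks whether a list moves on balance one way. The same held for the 9 calls among the means and the 9 over time. Members of a list that passed the test per gene are counted over all probe sets and adjusted over the list alone.

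Genes named in the text follow a rule. For a metal's mean over months these are the 12 highest and 8 lowest log2 changes among genes that passed and had the same sign in every month. For a month they are the 5 highest and 5 lowest among genes that passed and whose 3 metal arrays all lay beyond the 3 tantalum arrays; chance gives such a separation to 10% of genes. For each list they are up to 4 members with the smallest adjusted p in that metal, taken for a month from that month's test, and any member needed to show a count. The rule also takes 10 in each direction for time, 5 for a change between months and 10 for differences among metals. The text names a part of these. The groups, the comparisons, their tests, the lists, this rule and the alternatives, apart from those said to have been added, were chosen before the data were examined.

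Alternatives to the main analysis were the replicate number as a block within each month, leaving out the dimmest 30% of probe sets, a second quantile normalization, an intensity trend with robust hyperparameters, array weights, only the arrays of the same month or the 6 arrays compared, adjustment over all 31 comparisons together, the other metals as the reference, a stricter threshold of 0.01 for shared genes, and leaving out each array in turn. In a comparison of 3 pools with 3, leaving out an array leaves 2, and the shared estimate of the spread still gives a test. Added after the data were seen were the other metals as the reference at single months, a loess correction within each 1-month array for lead, and the list tests without single arrays. Replicate numbers were taken to pair arrays whose residuals correlated above 0.1. This held in 13 of 31 month comparisons: all 8 at 6 months, 5 of 7 at 12 and 0 at 1 or 3. Copper and depleted uranium at 12 months had lows of 0.07 and 0.09. Block values stand beside those results where they differ.

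The procedure was tested on 22954 simulated probe sets with the design of cobalt at 3 months. Changes of 0.5, 1 and 2 log2 were recovered in 34.3% of 67 probe sets, 95.5% of 67 and 100% of 66. Of 164 calls 11 were false, which need not hold for real arrays. Because all metals share the tantalum arrays, overlaps between metals were set beside 100 simulations of unchanged metals against shared controls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.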

Results

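Rats received pellets of 1 of 9 metals in the gastrocnemius, cylinders 1 mm across and 2 mm long, and muscle was taken 1, 3, 6 or 12 months later. Tantalum pellets served as the implanted control, so that each comparison asks what a metal did beyond surgery and a foreign object. Each of the 35 groups has 3 arrays, and 8 rats were assigned to each metal and month. Levels below are log2 values, mean ± SD of 3 arrays, and differences are log2 values, metal minus tantalum, ± SE from the model. Arrays of the whole set resembled each other closely: the lowest mean correlation of an array with the others was 0.970.

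The response depended on the metal and on the month. Cobalt and nickel at 3 months and lead at 1 month changed the most probe sets, 1254, 784 and 693. At 6 months, 0 probe sets passed for any of the 8 metals in limma, with between 1129 (aluminum) and 2115 (iron) at an unadjusted p below 0.05. Of the 34 gene lists, 10 shifted in at least 1 comparison of a metal with tantalum, and 24 in none. Of 1462 list tests 34 passed, and 0 of these had a median, mean and test that differed in sign. Fitted to the 6 arrays compared alone, cobalt and nickel at 3 months, depleted uranium at 12 months and lead at 1 month had 1040, 351, 18 and 4 probe sets, and every other month comparison had 0. Against the other metals in place of tantalum 0 were left for depleted uranium and cobalt at 1 month, cobalt and copper at 12 months, and the means of depleted uranium and lead.

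**Figure D1:**
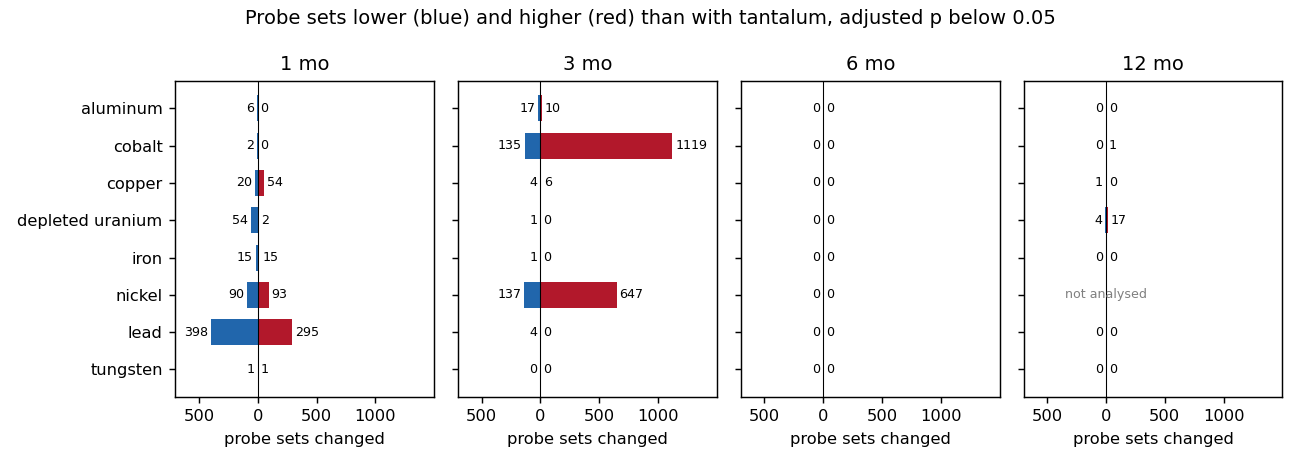
Probe sets past an adjusted p of 0.05 for each metal against tantalum of the same month, with those higher drawn to the right of 0 and those lower to the left. Cobalt reaches 1119 higher at 3 months, and the bars of 6 months are at 0.

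At 3 months, cobalt muscle held more transcript of chemokines, of T, NK and B cell markers and of the heme oxygenase Hmox1 than tantalum muscle. Cxcl13, a chemokine that attracts B cells, was at 11.70 ± 0.42 against 7.88 ± 2.1 (SD, n = 3 each), a difference of 3.82 ± 0.67. Hmox1, which breaks down heme, was at 9.79 ± 0.43 against 5.97 ± 0.18, a difference of 3.82 ± 0.31. Ptprc, the pan-leukocyte surface protein CD45, rose by 3.36 ± 0.33. Klrk1, an activating receptor of natural killer (NK) and cytotoxic T cells, rose by 3.29 ± 0.23, and Cxcl9, an interferon-induced chemokine for T cells, by 3.29 ± 0.24. The adjusted p of these 5 genes was at most 1.15e-05, and all 3 cobalt arrays lay above all 3 tantalum arrays. Klrk1 was near background level in tantalum muscle (4.17 ± 0.34). Decreases were smaller: Or6b9, an olfactory receptor gene near background level (4.37 ± 0.05 against 5.31 ± 0.30), had a difference of -0.93 ± 0.21, and Plcl1, a phospholipase C-like signalling protein, had a difference of -0.72 ± 0.18. In all, 1254 of 22954 probe sets changed, 1119 higher and 135 lower, of which 454 and 8 by at least 2-fold.

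Lymphocyte genes made up the clearest group. Of 18 measured T, NK and B cell markers, 16 rose (16 adjusted over the list alone), with a median of 1.36 and an adjusted p of 7.7e-11 for the list. Among them were Ccl5, a T cell chemokine (2.33 ± 0.20), Cd2 (2.25 ± 0.15) and Cd3e (2.14 ± 0.21), which belong to the T cell surface, and Nkg7, a granule protein (1.86 ± 0.17). The granzyme genes Gzma (0.25 ± 0.21) and Gzmb (0.12 ± 0.20) did not pass. Of 9 MHC class II genes, which present antigen, 5 rose (7 adjusted over the list alone), including RT1-Da (2.29 ± 0.23), Cd74 (2.22 ± 0.26) and RT1-Ba (2.18 ± 0.24), with an adjusted p of 0.000365 for the list. The interferon list followed with 7 of 18 members (8 adjusted over the list alone; adjusted p = 0.000394), among them the GTPases Ifi47 (2.48 ± 0.20) and Gbp2 (2.00 ± 0.15) and the immunoproteasome subunit Psmb9 (1.79 ± 0.15). Of 20 chemokines and cytokines, 8 rose (9 adjusted over the list alone; adjusted p = 0.00174), with Il18 at 2.34 ± 0.23 and Ccl7, which attracts monocytes, at 1.98 ± 0.22. Like Klrk1, the genes Cd2, Cd3e, Nkg7, Il18, Ccl7, Cr2, Klrc3, Klrd1, Ms4a4c and Ccna2 lay below 5.45 in tantalum muscle of this month, the limit of the dimmest 30% of probe sets.

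Macrophage markers rose in 14 of 20 cases with cobalt at 3 months (17 adjusted over the list alone; median 0.98), among them Laptm5 (2.46 ± 0.22), Aif1 (2.01 ± 0.27), Fcer1g (1.91 ± 0.24) and the complement gene C1qb (1.88 ± 0.24). The list had an adjusted p of 0.0248, which became 0.0547 without cobalt replicate 3, 0.0543 and 0.0717 without tantalum replicates 1 and 3, and 0.0632 with the replicate block. Of 21 cell cycle genes, 4 rose (8 adjusted over the list alone), among them the proliferation marker Mki67 (1.85 ± 0.22) and cyclin Ccna2 (1.38 ± 0.24). The list's adjusted p of 0.00527 became 0.176 without the dimmest probe sets. In the NRF2 list of oxidative stress genes 5 of 20 rose (5 adjusted over the list alone), among them the aldo-keto reductase Akr1b8 (3.00 ± 0.32) and transketolase Tkt (0.94 ± 0.13), but the list did not pass (adjusted p = 0.07). Neither did iron and heme genes, with 4 of 18 (5 adjusted over the list alone; adjusted p = 0.255). Of 18 targets of the hypoxia factor HIF, 1 rose (1 adjusted over the list alone), the glucose transporter Slc2a1 (0.63 ± 0.15), whose call ended without cobalt replicate 3 (adjusted p = 0.0589) or tantalum replicate 3 (adjusted p = 0.136). That list had a median of -0.05, a mean of 0.00 and an adjusted p of 0.992. Of the matrix list 1 of 20 genes passed (5 adjusted over the list alone; adjusted p = 0.68), and of the list for muscle regeneration 0 of 15 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.971). Tantalum itself varied at this month: Cxcl13 was at 8.19 and 9.80 in replicates 1 and 2 and at 5.64 in replicate 3.

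**Figure D2:**
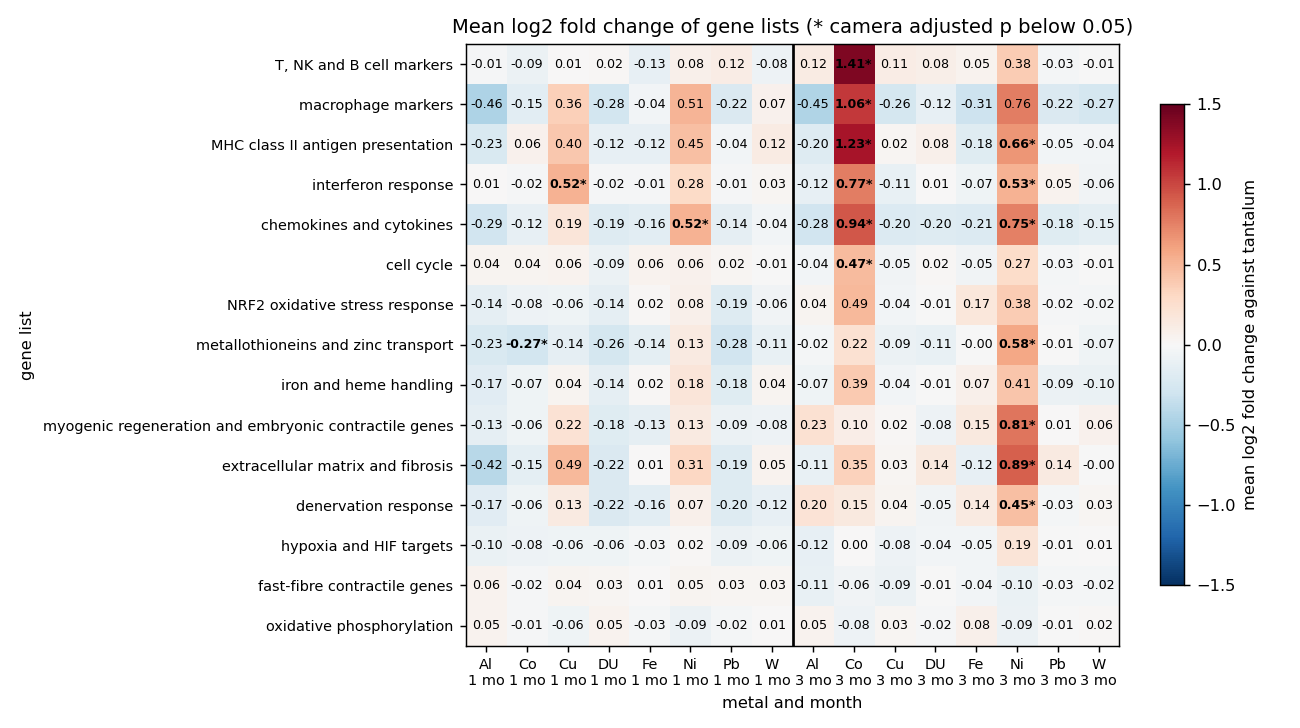
Mean log2 difference from tantalum of the members of each gene list, by metal, at 1 and 3 months, with the lists that passed marked. T, NK and B cell markers reach 1.41 with cobalt at 3 months.

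Outside 3 months, cobalt muscle differed little from tantalum muscle. At 1 month Sarnp, an mRNA export factor, and C1h9orf85 were lower, by -0.69 ± 0.13 and -0.72 ± 0.13 (adjusted p = 0.00713 for both). At 12 months the recycling GTPase Rab11b was higher by 0.61 ± 0.12 (adjusted p = 0.0469), and at 6 months 0 probe sets passed in limma (1334 at an unadjusted p below 0.05). Hmox1 had differences of -0.18, 3.82, 0.33 and 0.21 at 1, 3, 6 and 12 months, and Klrk1 of 0.04, 3.29, -0.14 and -0.05. A test of the change between months passed for 960 probe sets, among them those of the complement receptor Cr2 and the NK receptor Klrc3 (635 without replicate 2 and 511 without replicate 3). With the replicate block, which pairs the arrays at 12 months, 6 genes passed there: Rab11b (0.61), Hba-a1 (0.75), Entrep3 (0.70), Pelp1 (0.65), Fto (0.47) and Trmt112 (0.37), the last 5 outside the rule for naming. The 2 genes of 1 month became 0 without cobalt replicate 1 or 2 or tantalum replicate 1, 6 without tantalum replicate 2 and 4 without tantalum replicate 3. The gene of 12 months was lost without cobalt replicate 2 or 3 or tantalum replicate 1 or 3, with 0 left each time.

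As a mean over the 4 months, 263 probe sets differed with cobalt, 239 higher and 24 lower. The higher genes with 1 sign at every month included Ms4a4c (0.85 ± 0.10), the NK receptor Klrd1 (0.80 ± 0.11) and Cr2 (0.76 ± 0.09), and the lower ones Fhl5 (-0.42 ± 0.08) and the macrophage elastase Mmp12 (-1.30 ± 0.36). T, NK and B cell markers shifted up, with 8 of 18 members passing (14 adjusted over the list alone; adjusted p = 6.6e-08), as did MHC class II genes with 4 of 9 (6 adjusted over the list alone; adjusted p = 0.00549, and 0.0619 without cobalt replicate 3). The interferon list (5 of 18, 5 adjusted over the list alone; adjusted p = 0.0477) and the cell cycle list (2 of 21, 3 adjusted over the list alone; adjusted p = 0.0489) passed by little. The interferon list lost its call without cobalt replicate 1 (0.159) or 3 (0.102), tantalum replicate 1 (0.153), 2 (0.0524) or 3 (0.159), or with the replicate block (0.114). The cell cycle list did so without cobalt replicate 1 (0.165) or 3 (0.0922), tantalum replicate 1 (0.169) or 2 (0.106), with the replicate block (0.104) or without the dimmest probe sets (0.0752). The count was 173 without tantalum replicate 1, and the call of Mmp12 ended without any of 5 of the 6 replicates. At 1 month the metallothionein and zinc transport list was lower with cobalt, with a median of -0.26 but 0 of 9 members passing (0 adjusted over the list alone; adjusted p = 0.0147). Its adjusted p was 0.0547 and 0.125 without cobalt replicates 1 and 3, 0.0566 without tantalum replicate 2 and 0.108 without the dimmest probe sets.

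Nickel at 3 months raised the heme oxygenase Hmox1 and metallothioneins together with genes of immature muscle and of connective tissue. Hmox1 was at 9.27 ± 0.66 against 5.97 ± 0.18 (SD, n = 3 each), a difference of 3.30 ± 0.31, and the metallothionein Mt1, which binds zinc and copper, at 10.34 ± 0.71 against 7.25 ± 0.15, a difference of 3.09 ± 0.24. Akr1b8 rose by 2.90 ± 0.32, Tnnt2, the troponin T of heart and fetal muscle, by 2.65 ± 0.24, and Sfrp2, a secreted Wnt antagonist, by 2.65 ± 0.34. The adjusted p of these 5 was at most 2.29e-08, and all 3 nickel arrays lay above all 3 tantalum arrays. Among the decreases were those of Chac1, a glutathione-degrading stress gene (-0.98 ± 0.29), the mitochondrial ribosomal gene Mrpl38 (-0.74 ± 0.13) and the clock repressor Nr1d1 (-0.72 ± 0.18). In all, 784 probe sets changed, 647 higher and 137 lower, of which 190 and 2 by at least 2-fold.

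The list for muscle regeneration and embryonic contractile genes rose with nickel at 3 months in 6 of 15 members (9 adjusted over the list alone; adjusted p = 0.000177): besides Tnnt2, Actc1, the cardiac and fetal actin (2.1 ± 0.35), Myh3, embryonic myosin (1.85 ± 0.21), and Myl4, its light chain (1.65 ± 0.22). Of 20 matrix genes 15 rose (19 adjusted over the list alone; adjusted p = 0.00527), among them Lum (1.45 ± 0.24), Timp1 (1.15 ± 0.20), Mmp2 (1.11 ± 0.20) and the fibrillar collagen Col3a1 (1.09 ± 0.23). Of 9 metallothionein and zinc transport genes 3 rose (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.00573): Mt1, Mt2A (1.95 ± 0.24) and the zinc importer Slc39a14 (0.47 ± 0.11). The list's median was 0.12 and its mean 0.58. Chemokines and cytokines rose in 6 of 20 cases (14 adjusted over the list alone; adjusted p = 0.000601), with Ccl7 (2.05 ± 0.22), Ccl2 (1.6 ± 0.25) and Ccl3 (1.57 ± 0.21). Interferon genes rose in 8 of 18 (10 adjusted over the list alone; adjusted p = 0.00276), with Ifi47 (1.12 ± 0.20) and Gbp2 (0.84 ± 0.15).

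Of 9 MHC class II genes 4 rose with nickel at 3 months (6 adjusted over the list alone), including RT1-Da (1.31 ± 0.23) and RT1-Db1 (1.12 ± 0.20). The list's adjusted p of 0.0315 became 0.0849 without nickel replicate 3, 0.0904 without tantalum replicate 1, 0.0582 without the dimmest probe sets and 0.0675 with the replicate block. Of 13 genes of the denervation list 4 rose (9 higher and 1 lower adjusted over the list alone), among them Ankrd1, a stretch-responsive muscle protein (1.30 ± 0.31), and the transcription factor Runx1 (0.57 ± 0.14). The list's adjusted p of 0.0248 became 0.0595 without tantalum replicate 2 and 0.0675 with the replicate block. Macrophage markers rose in 11 of 20 cases (15 adjusted over the list alone), with C1qb at 1.68 ± 0.24 and Fcer1g at 1.6 ± 0.24, but the list did not pass (adjusted p = 0.0547). Neither did T, NK and B cell markers (3 of 18, 8 adjusted over the list alone; adjusted p = 0.0547) or iron and heme genes (4 of 18, 6 adjusted over the list alone; adjusted p = 0.0547), of which the iron exporter Slc40a1 rose by 1.51 ± 0.21. Of the HIF targets 2 of 18 rose (2 adjusted over the list alone; adjusted p = 0.127), Slc2a1 (1.33 ± 0.15) and the oxidoreductase Ero1a (0.85 ± 0.14). The count of 784 was 419 and 438 without nickel replicates 1 and 2 and 485 without tantalum replicate 3; 351 passed with the 6 arrays alone. Calls of single genes ended for Slc39a14 without nickel replicate 2 or tantalum replicate 2 and for Runx1 without tantalum replicate 1. Chac1 lost its call without nickel replicate 1 or 2 or tantalum replicate 1 or 3, and Nr1d1 without nickel replicate 1 or 2 or tantalum replicate 1.

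**Figure D3:**
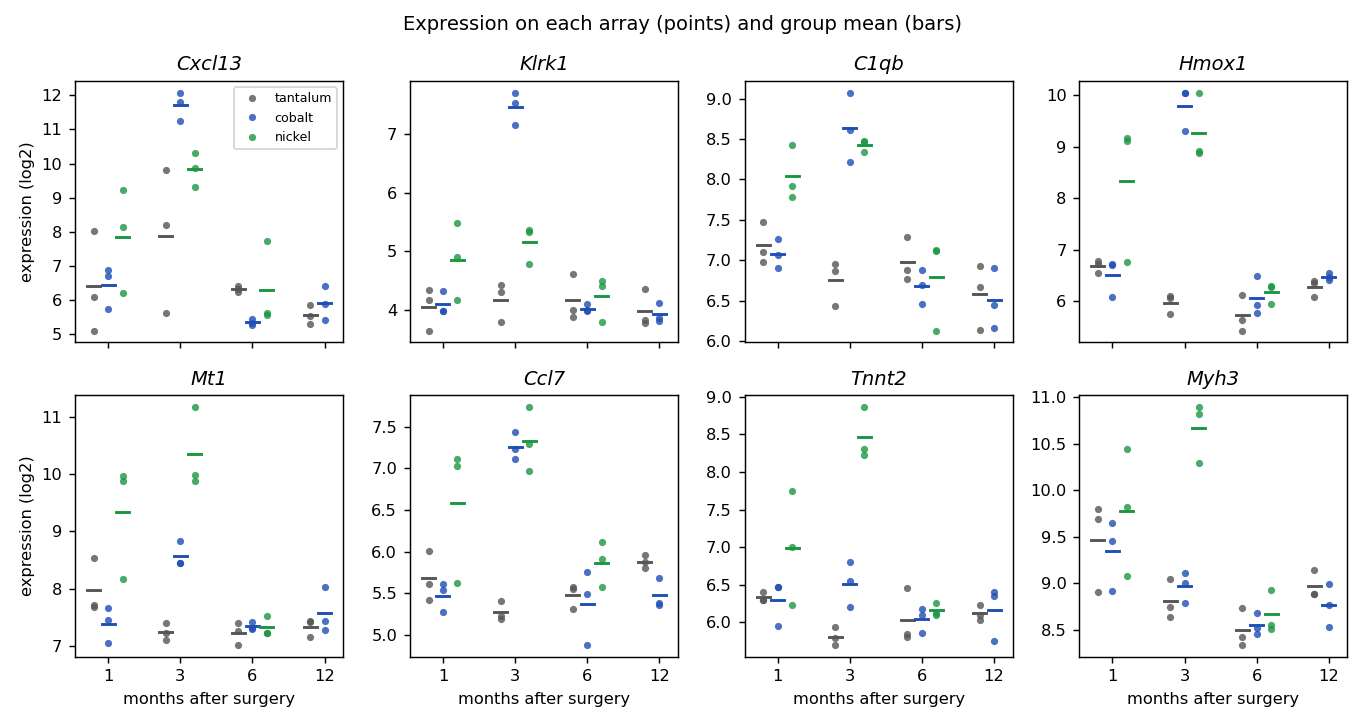
Log2 level on each array of genes named for cobalt and nickel, by month, for cobalt, nickel and tantalum. At 3 months Hmox1 is at a mean of 9.79 with cobalt and 9.27 with nickel, against 5.97 with tantalum.

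At 1 month nickel muscle already held more chemokine transcript. Ccl6 was higher by 1.39 ± 0.27, Ccl3 by 1.36 ± 0.21, and the neutrophil chemokine Cxcl2 by 1.20 ± 0.20, and 4 of 20 chemokines and cytokines rose (9 adjusted over the list alone; adjusted p = 0.0108, but 0.0566 and 0.122 without nickel replicates 2 and 3). Of 20 macrophage markers 2 rose (11 adjusted over the list alone), with a median of 0.53 and an adjusted p of 0.218 for the list, and of 9 MHC class II genes 2 rose (4 adjusted over the list alone; adjusted p = 0.164). Hmox1 rose by 1.66 and Mt1 by 1.35. Emb, an adhesion protein (1.15 ± 0.27), and Slc11a1, a metal transporter of phagosomes (1.11 ± 0.28), were also higher, while Cacng6, a calcium channel subunit of muscle (-0.97 ± 0.16), the glycosyltransferase Extl3 (-0.91 ± 0.16) and the growth factor Vegfb (-0.85 ± 0.16) were lower. In all 183 probe sets changed, 93 higher and 90 lower. The 3 nickel pools differed from each other: Hmox1 was at 6.76 in replicate 1 and at 9.10 and 9.16 in replicates 2 and 3, and Mt1 at 8.18 against 9.96 and 9.88. The count was 313 without nickel replicate 1, 104 and 39 without replicates 2 and 3, and 78, 70 and 352 without tantalum replicates 1, 2 and 3.

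At 6 months 0 probe sets passed with nickel in limma (1365 at an unadjusted p below 0.05), and 1 with the replicate block that pairs the arrays there. A test of the change between months passed for 281 probe sets (506 with the block), among them those of Mt1, Tnnt2, the chaperone Pdia4, the cadherin Fat1 and the asparagine synthetase Asns (67 without replicate 1 and 48 without replicate 2). As a mean over 1, 3 and 6 months 649 differed (1143 with the block), 423 higher and 226 lower. Hmox1 (1.80 ± 0.18), Mt1 (1.52 ± 0.14), Tnnt2 (1.15 ± 0.14) and Ccl7 (1.11 ± 0.13) had differences above 0 at every month, and Ccl9 (-0.91 ± 0.21) and Rab9a (-0.50 ± 0.09) below 0. None of these genes passed at 6 months. Chemokines and cytokines shifted up, with 8 of 20 members (11 adjusted over the list alone; adjusted p = 0.000376), as did interferon genes (5 of 18, 10 adjusted over the list alone; adjusted p = 0.0123), regeneration genes (3 of 15, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0258) and MHC class II genes (5 of 9, 5 adjusted over the list alone; adjusted p = 0.0274). The last 3 calls were lost with the replicate block (0.0516, 0.0721 and 0.0615) and without single replicates: interferon without nickel replicate 2 (0.0664), regeneration without tantalum replicate 3 (0.0792), and MHC class II without nickel replicate 2 (0.0664) or 3 (0.116) or tantalum replicate 1 (0.0970). The count was 305 and 371 without nickel replicates 2 and 3 and 336 and 357 without tantalum replicates 1 and 2.

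Cobalt and nickel at 3 months changed many of the same genes, with differences between lists. They shared 438 higher probe sets, where independent sets would share 31.5, and 34 lower ones (0.806), and 0 moved in opposite directions. Of the macrophage markers 11 rose with both metals, of MHC class II genes 4 and of interferon genes 5, and of the unfolded protein and amino acid stress genes 5 did: Asns, Hspa5, Hsp90b1, Pdia4 and Psat1. By their calls against tantalum the matrix list shared 1 gene, Mmp2, of the 15 that rose with nickel, and the T, NK and B cell list 3 of the 16 that rose with cobalt. Compared directly, 504 probe sets differed, 387 higher with cobalt and 117 with nickel. Of 18 T, NK and B cell markers 12 were higher with cobalt (median 1.17), and of 15 regeneration genes 5 with nickel. Higher with cobalt, and 0 with nickel, were 4 of 9 MHC class II, 5 of 18 interferon and 1 of 20 macrophage genes. Mt1, Mt2A and 2 of 18 HIF targets were higher with nickel, and 2 of 20 chemokines and cytokines with each metal. All 20 matrix genes were lower with cobalt than with nickel (median -0.52), and 3 passed: Lum (-0.97 ± 0.24), Tnc (-0.92 ± 0.25) and Thbs2 (-0.89 ± 0.23). The others did not, among them Mmp2 (-0.45 ± 0.20) and Col1a1 (-0.41 ± 0.25). Klrk1 was higher with cobalt (2.30 ± 0.23, cobalt minus nickel), and Tnnt2 (-1.95 ± 0.24) and Myh3 (-1.70 ± 0.21) were higher with nickel. As a mean over months the metals shared 123. Both metals were compared with the same tantalum arrays, and the correlation of their changes across genes was 0.735 at 3 months, where unchanged metals gave 0.512 on average and 0.884 at most over 100 simulations. The covariance was 0.0752 against a simulated mean of 0.0140 (SD 0.00744).

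At 1 month copper muscle held more interferon-induced transcript than tantalum muscle. The antiviral genes Rsad2 (1.11 ± 0.21), Mx1 (1.13 ± 0.26) and Mx2 (1.05 ± 0.24) and the GTPase Gbp2 (0.78 ± 0.15) rose, 4 of 18 measured members of the interferon list (12 adjusted over the list alone; adjusted p = 0.000191), and the list stayed past the threshold without any single array (highest adjusted p 0.00527). The matrix genes Lum (1.20 ± 0.24), Mmp14 (1.15 ± 0.21) and Mmp2 (1.00 ± 0.20) rose as well, 3 of 20 (8 adjusted over the list alone), though the list did not pass (adjusted p = 0.151). Also higher were Ctxn3 (1.51 ± 0.32), Tmem100 (1.33 ± 0.31), Ccl6 (1.23 ± 0.27), the granin Scg2 (1.15 ± 0.21) and Emb (1.14 ± 0.27), and among the lowest were Slc38a3, a glutamine transporter (-0.65 ± 0.15), Vamp2, a vesicle fusion protein (-0.64 ± 0.15), and Fxyd1, a regulator of the sodium pump (-0.57 ± 0.11). In all 74 probe sets changed, 54 higher and 20 lower. Replicates 1 and 3 carried most of the change: the mean of the interferon list was 6.77, 6.23 and 6.79 in copper replicates 1, 2 and 3 (6.05 to 6.11 in tantalum), and that of the matrix list 9.63, 8.66 and 9.40 (8.52 to 9.13 in tantalum). Rsad2 and Scg2 lay below 5.45 in tantalum muscle. Leaving out copper replicate 1 left 1 probe set, and the hair keratin-associated gene Krtap7-1 was at 9.93 in that replicate. The count was 199 and 12 without copper replicates 2 and 3 and 22, 4 and 141 without tantalum replicates 1, 2 and 3, and each copper gene named here lost its call without at least 1 array.

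At 3 months Mmp12 (-3.29 ± 0.71) and the chemokine Ccl9 (-1.99 ± 0.37) were lower with copper, and Htr1d (1.11 ± 0.23) and Cyp4x1 (0.86 ± 0.17) higher, among 10 probe sets that changed. Mmp12 was at 9.19 and 10.21 in tantalum replicates 1 and 2 of this month and at 5.16 in replicate 3. Against the other metals at 3 months Mmp12 differed by -2.02 (adjusted p = 0.0410), Ccl9 by -0.66 (adjusted p = 0.335), Htr1d by 0.92 (adjusted p = 0.00104) and Cyp4x1 by 0.57 (adjusted p = 0.0125). At 12 months Zfyve16, an endosomal protein, was lower by -0.80 ± 0.14, the 1 gene that passed. At 6 months 0 passed in limma (1595 at an unadjusted p below 0.05), and Pdzd11 (-0.60) and Rasa3 (-0.71), outside the rule for naming, passed with the replicate block that pairs those arrays. Over all months 9 differed (77 with the block), among them Siglec1, a macrophage lectin (0.46 ± 0.10), Tshb (0.51 ± 0.10) and Ccl9 (-0.93 ± 0.18), and 0 changed between months (1608 at an unadjusted p below 0.05, 42 changed with the block, and 6 and 25 without replicates 2 and 3). The 3-month count was 0 without copper replicate 1 or 2, 141 without replicate 3, 3 without tantalum replicate 1 or 2 and 21 without replicate 3. The mean count was 3, 5 and 110 without copper replicates 1, 2 and 3 and 1 without tantalum replicate 1 or 2, and Zfyve16 lost its call without copper replicate 1 or tantalum replicate 3 (0 left).

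At 1 month lead muscle held less transcript of a ferritin and of a tumor necrosis factor receptor. Ampd3, an AMP deaminase, was lower by -1.37 ± 0.35, the ferritin light chain Ftl1 by -1.18 ± 0.26, the receptor Tnfrsf1a by -1.06 ± 0.12, and the calcium-binding S100a11 and the survival factor Bcl2 by -0.93 each (± 0.24 and 0.22). Mt2A (-0.82 ± 0.24) and the zinc transporter Slc30a4 (-0.62 ± 0.16) fell too, 2 of 9 in their list (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.164). Higher were Pamr1 (0.95 ± 0.20), Ugt8, which makes myelin lipids (0.90 ± 0.26), Trpv5 (0.89 ± 0.19), Or6z7 (0.89 ± 0.22) and Zmynd15 (0.86 ± 0.15). Of 10 Schwann cell and myelin genes 1 rose (4 adjusted over the list alone; median 0.42, adjusted p = 0.409). In all 693 probe sets changed, 295 higher and 398 lower, and 0 of 34 lists passed (6 at an unadjusted p below 0.05, 9 with the preset correlation, 5 with fry). The changes went with intensity, with a Spearman correlation of -0.400 across probe sets between level and difference, and 286 passed after a loess correction, with a median absolute difference over the 693 of 0.48 in place of 0.57. The 693 kept a median of 0.34 against the other metals of 1 month. The count was 29 without lead replicate 2, 460 and 1230 without lead replicates 1 and 3, and 300 and 114 without tantalum replicates 1 and 2. Of the genes named for lead at 1 month, Tnfrsf1a, Pamr1 and Zmynd15 kept their calls without each of the 6 arrays.

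Later lead groups differed less. At 3 months Psmf1, a proteasome inhibitor, was lower by -0.57 ± 0.11, 1 of 4 probe sets that changed, all lower. At 6 and 12 months 0 passed in limma (1909 and 1574 at an unadjusted p below 0.05). With the replicate block, which pairs the arrays at both months, Prmt9, outside the rule for naming, passed at 6 months (-0.48). Over the months 32 differed (864 with the replicate block), 16 higher and 16 lower, with Ggt6 (0.39 ± 0.08) and Pdzd11 (-0.33 ± 0.06) among them, and 35 changed between months (168 with the block), Tnfrsf1a among them. The 3-month count was 0, 1 and 2 without lead replicates 1, 2 and 3, and 1, 0 and 20 without those of tantalum. The mean count was 248, 0 and 276 without lead replicates and 4, 189 and 15 without tantalum replicates, and the count between months was 0 without replicate 2 and 16 without replicate 3.

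With depleted uranium at 1 month, most genes that changed were lower. Ftl1 differed by -1.15 ± 0.26, Ncam1, an adhesion molecule of nerve and regenerating muscle, by -0.91 ± 0.19, Cacng6 by -0.86 ± 0.16, Unc13b, a vesicle priming protein, by -0.77 ± 0.17, and Sarnp by -0.74 ± 0.13, among 54 lower and 2 higher probe sets. With the other metals of 1 month as reference, or with the 6 arrays alone, 0 passed. Of the 54 lower ones 47 were also lower with lead at the same month, where 0.936 would be shared by independent sets. Unchanged metals compared with the same tantalum arrays shared 45 at most in 100 simulations. At 12 months 21 passed (100 with the replicate block). Or13c3g (1.11 ± 0.26) and Pate14l2 (0.87 ± 0.19) were higher, and Trmu (-0.90 ± 0.16), Hddc2 (-0.70 ± 0.14) and Rmdn1 (-0.47 ± 0.11) lower. At 3 months 1 passed, at 6 months 0 in limma (1274 at an unadjusted p below 0.05), and 4 each for the mean over months, which included C1h9orf85 (-0.32 ± 0.07), and for the change between months (40 and 85 with the replicate block). The metallothionein and zinc transport list was lower as a mean over months, with a median of -0.14 and 0 of 9 members passing (1 lower adjusted over the list alone; adjusted p = 0.0274). It did not pass without depleted uranium replicate 2 (0.0872) or 3 (0.116), tantalum replicate 1 (0.159) or 3 (0.0642), without the dimmest probe sets (0.203) or with the replicate block (0.0521). The count at 1 month was 13, 9 and 2 without depleted uranium replicates 1, 2 and 3 and 16, 11 and 24 without those of tantalum. At 12 months it was 1, 12 and 48, and 13, 0 and 4. The single probe set of 3 months was lost without depleted uranium replicate 2 or tantalum replicate 1 or 2 (7 without tantalum replicate 3), the mean count was 0, 2 and 2 without depleted uranium replicates 1, 2 and 3, and that between months 0 and 1 without replicates 1 and 2.

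Iron at 1 month stood out by epithelial and hair genes. Krtap7-1, a hair keratin-associated protein, was at 8.17 ± 1.08 against 5.71 ± 0.85, a difference of 2.45 ± 0.51, and the gap junction gene Gjb2 (1.23 ± 0.26), the hair follicle keratin Krt73 (1.11 ± 0.24) and the desmosomal genes Dsc3 (1.04 ± 0.20) and Perp (1.03 ± 0.22) were higher. In a list of 18 skin and hair follicle genes, written after these values were seen, the means of the iron arrays lay above the tantalum mean by 0.47, 1.07 and 0.98, and copper replicate 1 and tungsten replicate 1 of that month by 1.23 and 0.76. Lower were B4galt5 (-0.80 ± 0.17), Cacng6 (-0.68 ± 0.16), Vamp2 (-0.62 ± 0.15), Sarnp (-0.59 ± 0.13) and the methyltransferase activator Trmt112 (-0.59 ± 0.10), among 15 higher and 15 lower probe sets. Genes of iron and heme handling did not pass: 0 of 18 at 1 month (0 adjusted over the list alone; adjusted p = 0.992), and Hmox1 differed by 1.42 ± 0.31 at 3 months, with all 3 iron arrays above those of tantalum (adjusted p = 0.16). At 3 months 1 probe set passed, and at 6 months, 12 months, for the mean and for the change between months 0 did in limma (2115, 1077, 2426 and 1171 at an unadjusted p below 0.05), with 24 for the mean and 1 between months under the replicate block. The count at 1 month was 9 and 6 without iron replicates 2 and 3 and 14 and 5 without tantalum replicates 1 and 2, and of the 10 genes named by rule Trmt112 alone kept its call without each array. The 3-month count was 0, 2 and 0 without iron replicates 1, 2 and 3 and 0, 0 and 5 without those of tantalum. The count for the mean was 1 and 4 without tantalum replicates 1 and 3, and that between months 9 and 4 without replicates 1 and 3.

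With aluminum at 3 months 0 of 34 lists passed, and of the genes that changed some belong to leukocytes. The tetraspanin Cd53 (-1.60 ± 0.28), the oxidase subunit Cybb of phagocytes (-1.44 ± 0.30) and the lymphocyte receptor Slamf6 (-1.30 ± 0.26) were lower, while the T cell receptor Cd6 (1.04 ± 0.21) and the potassium channel Kcnma1 (1.09 ± 0.23) were higher, and the myogenic factor Myod1 was lower (-0.90 ± 0.20). In all 27 probe sets changed, 10 higher and 17 lower. Of 20 macrophage markers 1 was lower (4 adjusted over the list alone; adjusted p = 0.503), and of 18 T, NK and B cell markers 0 passed (0 adjusted over the list alone; adjusted p = 0.753). Tantalum replicates 1 and 2 held more Cd53 at this month (7.97 and 8.22) than replicate 3 (7.21). Against the other metals, which include cobalt and nickel, Cd53 differed by -1.45 (adjusted p = 1.47e-05), Slamf6 by -0.85 (adjusted p = 0.00884) and Cybb by -0.80 (adjusted p = 0.0544). In that comparison Cd6 differed by 0.63 (adjusted p = 0.0178), Kcnma1 by 0.71 (adjusted p = 0.0137) and Myod1 by -0.48 (adjusted p = 0.0837). Of 12 slow-fibre contractile genes 0 rose (9 adjusted over the list alone), with a median of 0.78 and an adjusted p of 0.498 for the list. The count was 1, 256 and 4 without aluminum replicates 1, 2 and 3 and 0, 1 and 33 without those of tantalum.

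At 1 month aluminum lowered Ly6e, an interferon-induced surface protein (-0.88 ± 0.18), the transport gene Sec23b (-0.73 ± 0.15), Fxyd1 (-0.64 ± 0.11), Tnfrsf1a (-0.56 ± 0.12) and Rhog (-0.54 ± 0.11), 5 of 6 probe sets that changed, all lower. As a mean over months 43 differed (404 with the replicate block, which pairs the arrays at 6 and 12 months), with Cd53 at -0.72 ± 0.14 and Il20rb at 0.33 ± 0.06, and 3 changed between months (55 with the block). At 6 and 12 months 0 passed in limma (1129 and 2143 at an unadjusted p below 0.05). With the replicate block, which pairs the arrays at both months, 5 passed at 12 months, among them Ltk (0.81), Ripk3 (0.68), Lysmd3 (-0.57) and Eif4e (-0.37), which are outside the rule for naming. The 1-month count was 1, 0 and 1 without aluminum replicates 1, 2 and 3 and 21 without tantalum replicate 2. Without aluminum replicate 2 the 6-month count was 1. The mean count was 0, 15 and 72 without aluminum replicates and 7, 191 and 15 without those of tantalum, and the count between months was 0 without replicate 1.

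Tungsten muscle was the closest to tantalum muscle. At 1 month Sval1 was higher (0.96 ± 0.18) and Acsbg2, an acyl-CoA synthetase, lower (-0.82 ± 0.16). At 3, 6 and 12 months 0 probe sets passed in limma (882, 1355 and 1190 at an unadjusted p below 0.05), and 0 for the mean and for the change between months (1435 and 1048). Of 136 list tests 0 passed (5 at an unadjusted p below 0.05, 12 with the preset correlation, 0 with fry). The 1-month count was 1, 7 and 0 without tungsten replicates 1, 2 and 3 and 0, 1 and 5 without those of tantalum, and Sval1 and Acsbg2 each lost their call without at least 3 arrays. Without tantalum replicate 3 counts of 0 became 4 at 3 months and 1 for the mean, and without replicate 3 that for the change between months became 2.

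A set of 14 probe sets was lower in at least 4 metals at 1 month, and 0 were higher in as many. Of its 11 named genes, Fxyd1 and Sarnp were lower with 6 metals, Trmt112, Vamp2, Stmp1, Dennd6b and C1h9orf85 with 5, and Cacng6, Rhog, Slc38a3 and the translation factor Eif5a with 4. This set was chosen after the values were seen. The median shift below tantalum was 0.56 over the 7 metals other than tungsten, and 0.06 with tungsten. At 3 months it was 0.10 over the 7 metals and 0.08 with tungsten, and at 6 and 12 months -0.04 and -0.14 over the metals other than tungsten. All 21 arrays of the 7 metals lay between 0.34 and 0.72 below the tantalum mean, the tungsten arrays between 0.00 and 0.11.

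Compared without tantalum, the 8 other metals differed among themselves at 1117 probe sets over months 1, 3 and 6. Mt1 had the highest F, with a mean of 9.00 with nickel, followed by Hmox1 with 7.93 with nickel, 7.45 with cobalt and between 6.05 and 6.94 with the other metals. Cd53, Lcp1, Ccl3 and Ccl7 were highest with nickel, and Klrc3, Klrk1, Cxcl11 and the retinoid-induced Rarres1 with cobalt. The count was 570 and 597 without replicates 2 and 3.

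In tantalum muscle, matrix transcripts fell over the year after surgery. Col1a1 was lower than at 1 month by 1.32 at 3 months, 1.87 at 6 months and 2.43 at 12 months (differences of -1.32, -1.87 and -2.43, each ± 0.25), and Sparc, a collagen-binding matrix protein, and Postn, a matricellular protein, differed by -1.67 ± 0.16 and -1.97 ± 0.31 at 12 months. Of 20 matrix genes 3 fell at 3 months (13 adjusted over the list alone; adjusted p = 0.0332), 11 at 6 months (18 adjusted over the list alone; adjusted p = 0.0123) and 15 at 12 months (18 adjusted over the list alone; adjusted p = 0.00479). Of 11 endothelial markers 4 fell at 6 months (7 adjusted over the list alone; adjusted p = 0.0443) and 6 at 12 months (7 adjusted over the list alone; adjusted p = 0.0206), with Eng at -0.83 ± 0.14 and Cdh5 at -0.60 ± 0.12, and of 18 iron and heme genes 5 fell at 12 months (5 adjusted over the list alone; adjusted p = 0.0423), with Ftl1 at -1.24 ± 0.26 and the transferrin receptor Tfrc at -0.88 ± 0.18. Tmem196 (2.22 ± 0.28) and Hook1, which links vesicles to microtubules (1.91 ± 0.23), were higher at 12 months, and Nr1d1 at 3 months (1.18 ± 0.18). In all 51, 1093 and 1801 probe sets changed at 3, 6 and 12 months. Rats also aged over this time, and the labels give no array batch, so that age, time after surgery and processing cannot be separated. The counts were 27, 0 and 27 without replicates 1, 2 and 3 at 3 months, 367, 669 and 221 at 6 months and 856, 914 and 801 at 12 months. List calls were lost without 1 replicate as follows: matrix at 3 months without replicate 1 (0.0510) or 3 (0.403), at 6 months without replicate 3 (0.222) and at 12 months without replicate 3 (0.0883), endothelial without replicate 2 at 6 (0.349) and 12 months (0.173), and iron and heme without replicate 1 (0.0652), 2 (0.145) or 3 (0.0940). The replicate block ended the matrix call at 3 months (0.0535), the endothelial call at 6 months (0.0791) and the iron and heme call (0.0516), and leaving out the dimmest probe sets ended the same 3 (0.0571, 0.0911 and 0.0781) and the endothelial call at 12 months (0.0571).

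**Figure D4:**
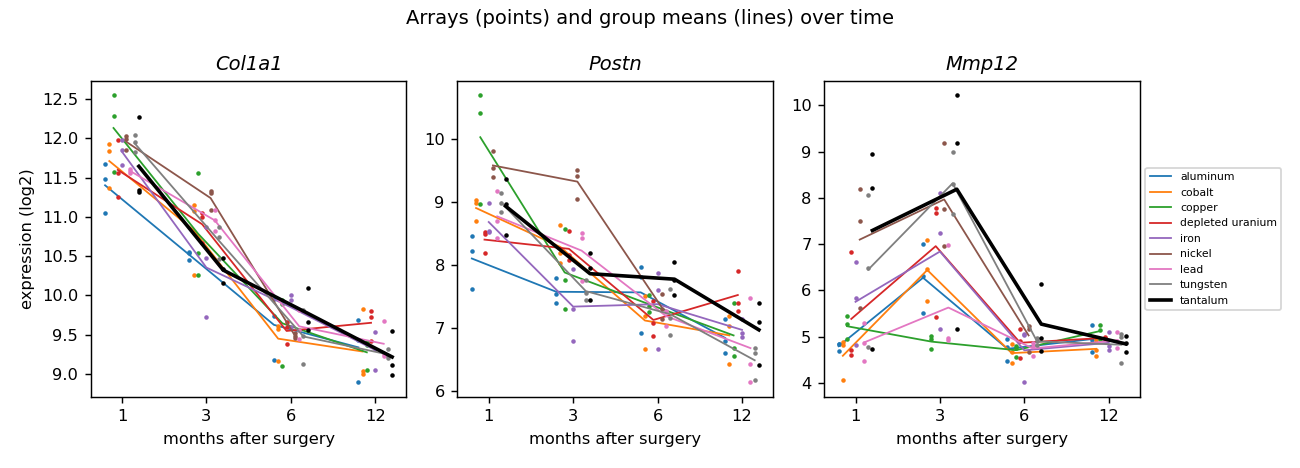
Log2 level of Col1a1, Postn and Mmp12 on each array (points) and group means (lines) against the month after surgery, by metal. Members of the matrix list, which is not drawn as a whole, differ by a mean of -1.03 between 12 and 1 months over the 8 metals with both.

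The same change appeared over the 8 metals with arrays at 1 and 12 months, tantalum and 7 others. Col1a1 (-2.39 ± 0.09), Postn (-1.95 ± 0.11), Col1a2 (-1.94 ± 0.09), Col3a1 (-1.81 ± 0.08) and Sparc (-1.66 ± 0.06) fell, as did the tendon gene Tnmd (-1.44 ± 0.13), and 19 of 20 matrix genes were lower and 1, Mmp3, higher (0.21 ± 0.07), the same 19 and 1 adjusted over the list alone (adjusted p = 0.00479). All 11 endothelial markers fell (11 adjusted over the list alone; adjusted p = 0.00479), with Eng at -0.70 ± 0.05, and 9 iron and heme genes fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.0173), with Tfrc at -1.16 ± 0.06. Of 12 slow-fibre contractile genes 10 fell (10 adjusted over the list alone), with a median of -0.51 and an adjusted p of 0.499 for the list. Tmem196 (1.74 ± 0.10), the muscle-secreted peptide Ostn (1.63 ± 0.13), Hook1 (1.62 ± 0.08) and the cell cycle inhibitor Cdkn1a (1.08 ± 0.08) were higher. In all 10128 probe sets changed, 5370 higher and 4758 lower. The iron and heme call was lost without replicate 1 (0.0546) or 2 (0.0594) and without the dimmest probe sets (0.0571), and Mmp3 lost its call without replicate 1 or 2.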

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

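The tests for lymph node tissue and for a single pool with cobalt, both loess tests with lead, every test against the other metals in place of tantalum, and all tests of the decreases shared at 1 month were chosen only after the result was seen.

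The results in this part stood out because the effect of a metal differed between months in the test of that change. Cobalt had the most such probe sets (960), and its leukocyte genes had F values of Cr2 70.5, Klrc3 62.2, Il2rb 56.3, Klrk1 53.6, Cd2 48.4, Ms4a4c 43.5, Laptm5 38.4, Ptprc 33.5, Cd3e 28.2, Nkg7 26.2, Klrd1 20.05, Fcer1g 19.7, C1qb 17.8 and Aif1 14.12. Its chemokine, interferon and MHC class II genes had Cxcl11 60.3, Gbp2 49.7, Cxcl9 48.2, Ifi47 42.04, Psmb9 38.96, Ccl5 35.3, Il18 30.3, RT1-Da 27.2, Ccl7 24.9, Cd74 21.2, RT1-Ba 21.04 and Cxcl13 9.66. Other cobalt genes had Hmox1 37.3, B3gnt5 31.9, Akr1b8 22.05, Tkt 17.4, Mki67 17.3, Rab11b 15.5, Sarnp 9.38, Ccna2 7.77, C1h9orf85 7.67 and Slc2a1 7.15.

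Nickel had 281 such probe sets. Genes of metal binding, transport and stress had F values of Mt1 37.99, Pdia4 29.1, Asns 23.6, Akr1b8 22.2, Hmox1 22.1, Slc2a1 20.8, Slc40a1 16.3, Mt2A 11.7, Slc11a1 10.2 and Ero1a 8.67. Muscle and connective tissue genes had Tnnt2 31.9, Fat1 26.4, Myh3 19.3, Mmp2 17.7, Sfrp2 15.3, Actc1 15.3, Lum 11.5, Timp1 9.27 and Myl4 8.70. Immune genes had Il18 20.4, C1qb 14.8, Ccl7 14.6, Ccl3 13.9, Ccl2 13.3, Fcer1g 10.998, Ccl6 10.53, RT1-Da 9.73 and Gbp2 9.31, and other nickel genes had Nr1d1 11.6, Mrpl38 10.1, Vegfb 9.94, Cacng6 9.46, Tent5c 9.35, Emb 9.35 and Extl3 8.56.

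Lead had 35 such probe sets, with F values of Tnfrsf1a 24.3, Trmt112 16.2, Psmf1 13.1, Rhog 12.1, Pigs 11.7 and Ftl1 9.77. Depleted uranium had 4, with Ubap2 13.4, Trmt112 12.1, Fxyd1 11.6 and Sarnp 11.002, and aluminum had 3, with Ripk3 12.95, Pgm2l1 11.7 and Fxyd1 10.8.

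Lymphocyte genes rose in cobalt muscle at 3 months, and the response was seen in all 3 pools: the lowest cobalt array lay 1.20 above the highest tantalum array in the mean of the list, and the list passed without each cobalt array (highest adjusted p 8.12e-10), which argues against 1 pool as the source. Against the other metals the list mean was 1.30 instead of 1.41, a share of 0.928, which argues against tantalum arrays that stand apart. Lymph node tissue taken with the muscle cannot be told apart from lymphocytes within it: genes of the node rose by a median of 1.11 over 18 genes and those of NK and effector cells by 1.26 over 16, a difference of -0.15 (permutation p = 0.716). Of 19 node genes 9 lay above the dim level in tantalum muscle and 1 was also in a planned list, and Ccl21 had the highest level (6.83). Infiltration into the tissue around the pellet may be a candidate explanation, and so may a node in the sample.

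After a loess correction, which took the correlation of level and difference from -0.400 to -0.019, 286 probe sets passed with lead at 1 month in place of 693, below the bound of 462, so that an intensity-dependent difference between arrays may add to the count. The 693, chosen for large differences, cannot show whether that trend is the whole cause. Their median difference went from 0.57 (median SE 0.15) to 0.48 (0.149), a share of 0.855 (interval over probe sets 0.837 to 0.879). All kept their sign. The count was 29 without lead replicate 2, as 1 pool that adds much of the difference would give (460 and 1230 without replicates 1 and 3, and 300 and 114 without tantalum replicates 1 and 2). Set against the other metals at 1 month, the 693 kept a median of 0.34, a share of 0.592 (interval 0.568 to 0.616) under the bound of 0.667, so that tantalum arrays that stand apart may be the source of a part. The count of 965 against these metals, above a bound written before it was seen, decides nothing for the 693, since only 286 of them are among the 965. A response to lead stays open for the rest, as does a larger share in 1 pool or 1 array.

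The 14 probe sets lower in at least 4 metals at 1 month share their tantalum reference. Tungsten differed from tantalum by a median of 0.057 at these probe sets against 0.56 for the other 7 metals, which argues against tantalum arrays that alone stand apart (bound 0.28, from which it differed with an interval over probe sets of -0.29 to -0.13). Over arrays the SE of the tungsten difference was 0.05. At 3 months the 7 metals lay 0.10 below tantalum, more than 2 standard errors (0.05), as a response common to the metals needs, but tungsten lay 0.084 below it too, so that a response that tungsten lacks cannot be told apart there (bound 0.049, interval of the difference -0.12 to 0.12). The direction then turned, with medians of -0.04 (SE 0.03) at 6 months and -0.14 (SE 0.04) at 12 months, while tantalum itself fell to 0.51 and 0.63 below its level of 1 month. A response to the metals at 1 month stays open, and so does a processing batch shared by tantalum and tungsten at that month, since the labels give no batch.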

How the results depend on the processing

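The replacement of tantalum by the other metals at single months, the loess correction at 1 month and the list tests without single arrays were chosen after seeing the data. Counts below are probe sets past the threshold, each with the count of the report in brackets, where the 2 differ by more than 1.5-fold. Over all alternatives other than leaving out arrays, 230 of 393 counts stayed within 1.5-fold, 58 were lower and the others higher. Of 1074 tests of named genes 1016 stayed on their side of the threshold with the same direction and 58 no longer passed, and of 136 list tests 114 stayed and 22 no longer passed. In these tests 0 genes and 0 lists reversed.

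The replicate block raised 33 of 52 counts and lowered 1, which belongs to a model with fewer degrees of freedom and another residual spread. Of the 358 named gene results 357 stayed and 1 no longer passed. For aluminum the counts were 86 (6) at 1 month, 1.1e+02 (27) at 3 months, rounded from 30 higher plus 75 lower, 5 (0) at 12 months, 404 (43) for the mean and 55 (3) between months, and for cobalt 38 (2) at 1 month and 6 (1) at 12 months. For copper the counts were 129 (74) at 1 month, 48 (10) at 3 months, 2 (0) at 6 months, 77 (9) for the mean and 42 (0) between months, and for depleted uranium 190 (56) at 1 month, 7 (1) at 3 months, 100 (21) at 12 months, 40 (4) for the mean and 85 (4) between months. For iron the counts were 63 (30) at 1 month, 0 (1) at 3 months, 24 (0) for the mean and 1 (0) between months, and for nickel 419 (183) at 1 month, 1259 (784) at 3 months, 1 (0) at 6 months, 1143 (649) for the mean and 506 (281) between months. For lead the counts were 1683 (693) at 1 month, 7 (4) at 3 months, 1 (0) at 6 months, 864 (32) for the mean and 168 (35) between months, and for tantalum against 1 month 172 (51) at 3 months, 2073 (1093) at 6 months and 2845 (1801) at 12 months. The cause was not tested.

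With array weights 18 of 52 counts were higher and 2 lower, and 346 of 358 named gene results stayed. Weighting gave aluminum 24 (6) at 1 month, 88 (27) at 3 months, 76 (43) for the mean and 9 (3) between months, and cobalt 1995 (1254) at 3 months. Weighting gave copper 143 (74) at 1 month, 306 (10) at 3 months, 44 (9) for the mean and 48 (0) between months, and depleted uranium 119 (56) at 1 month, 4 (1) at 3 months, 4 (21) at 12 months and 9 (4) for the mean. Weighting gave iron 0 (1) at 3 months and 22 (0) for the mean, and nickel 346 (183) at 1 month and 1445 (784) at 3 months. Weighting gave lead 11 (4) at 3 months and 64 (32) for the mean, and tantalum against 1 month 144 (51) at 3 months. The cause was not tested.

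A second quantile normalization raised 5 counts and lowered 5, and 45 of 358 named gene results no longer passed. Aluminum then had 26 (43) for the mean and 6 (3) between months, and cobalt 2 (1) at 12 months. Copper then had 6 (10) at 3 months, 2 (9) for the mean and 14 (0) between months, and depleted uranium 9 (4) between months. Iron then had 1 (0) between months, and lead 457 (693) at 1 month. Tungsten then had 1 (2) at 1 month. The cause was not tested.

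An intensity trend with a robust prior raised 3 counts and lowered 2. There aluminum had 5 (3) between months, and copper 5 (9) for the mean and 3 (0) between months. There iron had 2 (0) for the mean, and lead 2 (4) at 3 months. The cause was not tested.

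Leaving out the dimmest probe sets, so that fewer were tested, raised 8 counts and lowered 6. In that set aluminum had 14 (6) at 1 month, 47 (27) at 3 months, 109 (43) for the mean and 7 (3) between months, and cobalt 160 (263) for the mean. In that set copper had 5 (10) at 3 months and 14 (0) between months, and depleted uranium 5 (21) at 12 months and 8 (4) between months. In that set iron had 19 (30) at 1 month and 2 (0) for the mean, and lead 2 (4) at 3 months and 122 (32) for the mean. In that set tungsten had 1 (2) at 1 month.

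Fits to the arrays of the same month alone, with fewer degrees of freedom for the spread, raised 2 of 31 counts and lowered 12. By month aluminum had 1 (6) at 1 month and 13 (27) at 3 months, and copper 5 (74) at 1 month, 0 (10) at 3 months and 0 (1) at 12 months. By month iron had 14 (30) at 1 month and 0 (1) at 3 months, and nickel 100 (183) at 1 month. By month tungsten had 0 (2) at 1 month, and depleted uranium 0 (1) at 3 months and 42 (21) at 12 months. By month lead had 0 (4) at 3 months, and cobalt 3 (0) at 6 months and 0 (1) at 12 months.

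Fits to the 6 arrays compared raised 0 of 31 counts and lowered 16. From 6 arrays aluminum had 0 (6) at 1 month and 0 (27) at 3 months, and cobalt 0 (2) at 1 month and 0 (1) at 12 months. From 6 arrays copper had 0 (74) at 1 month, 0 (10) at 3 months and 0 (1) at 12 months, and depleted uranium 0 (56) at 1 month and 0 (1) at 3 months. From 6 arrays iron had 0 (30) at 1 month and 0 (1) at 3 months, and nickel 0 (183) at 1 month and 351 (784) at 3 months. From 6 arrays lead had 4 (693) at 1 month and 0 (4) at 3 months, and tungsten 0 (2) at 1 month.

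One adjustment over all 31 comparisons, which shares the threshold between strong and weak ones, raised 22 counts and lowered 4. Adjusted together, aluminum had 27 (6) at 1 month, 41 (27) at 3 months, 3 (0) at 6 months and 7 (0) at 12 months, and cobalt 16 (2) at 1 month, 790 (1254) at 3 months, 5 (0) at 6 months and 7 (1) at 12 months. Adjusted together, copper had 31 (10) at 3 months and 8 (0) at 6 months, and depleted uranium 5 (1) at 3 months, 4 (0) at 6 months and 39 (21) at 12 months. Adjusted together, iron had 8 (1) at 3 months and 10 (0) at 6 months, and nickel 115 (183) at 1 month, 400 (784) at 3 months and 6 (0) at 6 months. Adjusted together, lead had 164 (693) at 1 month, 7 (4) at 3 months, 1 (0) at 6 months and 4 (0) at 12 months, and tungsten 12 (2) at 1 month, 4 (0) at 3 months, 4 (0) at 6 months and 3 (0) at 12 months.

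With the other metals as reference in place of tantalum 14 of 39 counts were higher and 9 lower. Against other metals aluminum had 61 (6) at 1 month, 334 (27) at 3 months, 1 (0) at 6 months and 24 (43) for the mean, and cobalt 0 (2) at 1 month, 1896 (1254) at 3 months, 0 (1) at 12 months and 616 (263) for the mean. Against other metals copper had 185 (74) at 1 month, 208 (10) at 3 months, 0 (1) at 12 months and 1 (9) for the mean, and depleted uranium 0 (56) at 1 month, 3 (1) at 3 months, 48 (21) at 12 months and 0 (4) for the mean. Against other metals iron had 16 (30) at 1 month and 96 (1) at 3 months, and lead 15 (4) at 3 months and 0 (32) for the mean. Against other metals tungsten had 121 (2) at 1 month, 37 (0) at 3 months and 2 (0) for the mean. The cause was not tested.

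The loess correction lowered the count of lead at 1 month from 693 to 286. Of the 693 probe sets 215 still passed, and the median absolute difference of the 693 went from 0.57 to 0.48 with a median SE of 0.15 before and 0.149 after, so that smaller differences ended the calls. At an adjusted p below 0.01 cobalt and nickel shared 270 (472) probe sets at 3 months and 63 (123) for the mean over months, where each metal has fewer of its own.

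Leaving out 1 array of a group of 3, whose remaining 2 are assumed to vary like the other groups, moved 139 of 273 counts by more than 1.5-fold, 34 of them up and the others down. Counts for aluminum ran from 0 to 21 (6) at 1 month, 0 to 256 (27) at 3 months, 0 to 1 (0) at 6 months, 0 to 191 (43) for the mean and 0 to 4 (3) between months. Those for cobalt ran from 0 to 6 (2) at 1 month, 0 to 1 (1) at 12 months, 173 to 237 (263) for the mean and 511 to 654 (960) between months. Counts for copper ran from 1 to 199 (74) at 1 month, 0 to 141 (10) at 3 months, 0 to 1 (1) at 12 months, 1 to 110 (9) for the mean and 0 to 25 (0) between months. Those for depleted uranium ran from 2 to 24 (56) at 1 month, 0 to 7 (1) at 3 months, 0 to 48 (21) at 12 months, 0 to 5 (4) for the mean and 0 to 4 (4) between months. Counts for iron ran from 5 to 24 (30) at 1 month, 0 to 5 (1) at 3 months, 0 to 4 (0) for the mean and 0 to 9 (0) between months. Those for nickel ran from 39 to 352 (183) at 1 month, 419 to 935 (784) at 3 months, 305 to 572 (649) for the mean and 48 to 232 (281) between months. Counts for lead ran from 29 to 1230 (693) at 1 month, 0 to 20 (4) at 3 months, 0 to 276 (32) for the mean and 0 to 24 (35) between months. Those for tungsten ran from 0 to 7 (2) at 1 month, 0 to 4 (0) at 3 months, 0 to 1 (0) for the mean and 0 to 2 (0) between months. Counts for tantalum against 1 month ran from 0 to 27 (51) at 3 months, 221 to 669 (1093) at 6 months and 801 to 914 (1801) at 12 months. Those over all metals ran from 570 to 774 (1117) among the metals without tantalum. Cobalt at 3 months had 874 to 1141 (1254) and 12 against 1 month over 8 metals 7645 to 8790 (10128), all within 1.5-fold. Of 1788 tests of named genes 1171 stayed, 616 no longer passed, 1 newly passed and 0 reversed. Of 177 list tests 136 stayed, 41 no longer passed and 0 reversed. Fewer arrays raise the SE, and the report names the arrays. On each array between 88.5% and 94.9% of probe sets lay above the median of the control probe sets, which limits what the dimmest 30% can show.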

Other observations

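The lists of lymph node, NK and skin genes and the tests on them were chosen only after the results were seen, and so was the count of splits that keep the arrays of a month together or part the pairs. The splits themselves were planned.

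With cobalt at 3 months genes of B cells and of lymphoid follicles were higher: Cr2, a complement receptor of follicular cells, by 2.90, Cd37 by 2.65, the B cell receptor subunit Cd79b by 1.97, Bank1 by 1.75, and the chemokines Ccl19 by 1.71 and Ccl21 by 1.39. The chemokine receptors Ccr7 (0.98) and Cxcr5 (1.39) and the cytokine receptor Il7r (2.77) were higher too, and 13 of 19 node genes and 16 of 21 NK and effector genes passed. Pax5 (0.45) and Lef1 (0.28) did not pass. With nickel at 3 months Cr2 differed by 0.07 and Cd79b by 0.39.

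Skin and hair follicle genes were higher in iron muscle at 1 month, in a list written after such genes were seen, which holds the 8 of 18 that passed. Without these 8, 9 of the other 10 lay above 0, with a median of 0.45 (camera, unadjusted p = 0.00033, not part of the planned family). Over this list copper replicate 1 of the same month lay 1.23 above the tantalum mean and tungsten replicate 1 lay 0.76 above it, with Krtap7-1 at 9.93 and 8.67, while copper replicates 2 and 3 lay at -0.04 each. Of the 18 genes 9 lay above the dim level in tantalum muscle, with Tp63 highest (7.88), and 0 were in a planned list. No test here tells skin taken with the muscle from a change within it.

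Probe set TC0600003320.rn.2, which carries no gene symbol in the annotation used here, was the most raised of those unnamed with nickel at 3 months, at 13.14 ± 0.13 against 4.86 ± 0.35 (SD, n = 3 each). Probe set TC0400004145.rn.2 was at 12.51 ± 0.43 against 5.82 ± 0.33.

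Groups of 3 and 3 arrays can be split in 10 ways, too few for a share under 0.05, so that the real count is given here with the highest count of the other splits. Aluminum gave 6 against 2 at 1 month, 27 against 4 at 3 months, 0 against 1 at 6 months and 0 against 1 at 12 months, and cobalt gave 2 against 3 at 1 month, 1254 against 4 at 3 months, 0 against 3 at 6 months and 1 against 0 at 12 months. Copper gave 74 against 283 at 1 month, 10 against 59 at 3 months, 0 against 1 at 6 months and 1 against 1 at 12 months, and depleted uranium gave 56 against 2 at 1 month, 1 against 4 at 3 months, 0 against 0 at 6 months and 21 against 1 at 12 months. Iron gave 30 against 9 at 1 month, 1 against 7 at 3 months, 0 against 0 at 6 months and 0 against 0 at 12 months, and nickel gave 183 against 161 at 1 month, 784 against 10 at 3 months and 0 against 0 at 6 months. Lead gave 693 against 15 at 1 month, 4 against 6 at 3 months, 0 against 1 at 6 months and 0 against 0 at 12 months, and tungsten gave 2 against 4 at 1 month, 0 against 5 at 3 months, 0 against 1 at 6 months and 0 against 1 at 12 months. Tantalum compared with 1 month gave 51 against 16 at 3 months, 1093 against 4 at 6 months and 1801 against 3 at 12 months. The real count was met by 1 split, itself, or by 2, 3, 4 or 5 of the 10, and by all 10 where it was 0. In the 13 comparisons of 6 and 12 months whose replicate numbers pair the arrays the real count was 0 or 1, and the other splits gave 3 at most, whether or not they part the pairs. For copper at 1 month 1 other split changed 283 probe sets, and at 3 months 1 changed 59, several times the real count, which points to a structure among these arrays other than copper. Replicate 1 of copper at 1 month carried the skin and hair genes given above.

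For the other counts 100 splits were drawn. Some shares of splits as large, the real one included, were under 0.05, unadjusted. Among means these were aluminum (1 split: 43 probe sets against 7 at most) and depleted uranium (1: 4 against 3). So were nickel (2: 649 against 652) and lead (2: 32 against 92). Between months they were cobalt (2: 960 against 1211) and lead (1: 35 against 27). Others were 12 against 1 month (1: 10128 against 355) and among metals (1: 1117 against 16). Some fell to 0 without 1 replicate number in all months. These were the means of aluminum (1), depleted uranium (1) and lead (2), and lead between months (2). Chance cannot be excluded for the mean of copper (5; 9 against 36), nor for the change between months with aluminum (10; 3 against 7) and depleted uranium (5; 4 against 12). Where the real count was 0, all 100 splits gave as many: the means of iron (2 at most) and tungsten (3) and the change between months with copper (85), iron (8) and tungsten (7).

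For the mean of cobalt (12 splits as large; 263 against 777) and the change between months with nickel (5; 281 against 775) the share of splits does not exclude chance either, but these splits are no clean reference. All 11 other splits as large for cobalt, and all 4 for nickel, kept the 3 metal and 3 tantalum arrays of 3 months together or exchanged them whole, and so held the difference of that month. The splits that parted these arrays gave 1 probe set at most for cobalt and 135 for nickel. The same holds for the splits above the real count with 652 for the mean of nickel, 1211 for cobalt between months and 92 for the mean of lead, where the splits that parted the arrays of 3 months, or of 1 month for lead, gave 136, 28 and 4 at most. The copper splits with 36 for the mean and 85 between months parted the arrays of 1 month, and they point to a structure among these arrays other than copper.

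Where replicate numbers pair the arrays, at 6 and 12 months, the real split parts all pairs. So did 16 of the other splits with aluminum, cobalt and lead, too few to exclude chance. With nickel 37 did, and 40 with copper and depleted uranium. Among these the highest count for the mean was 0 with aluminum, 384 with cobalt, 30 with copper, 3 with depleted uranium, 154 with nickel and 2 with lead, and between months 5, 702, 76, 6, 775 and 27. The splits that kept a pair on 1 side gave 7, 777, 36, 1, 652 and 92 at most for the mean and 7, 1211, 85, 12, 575 and 21 between months.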
